A study of Drosophila melanogaster with 15 samples.

How the data were processed

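Total RNA from 20 wing imaginal discs per sample, of larvae kept at 25 °C, was labelled with Cy3 from 200 ng, per the labels' protocols, and hybridised to 1-colour Agilent arrays on 2 slides. Slide 1 held 8 arrays (3 GFP, 2 LacZ and 3 p35) and slide 2 held 7 (2 GFP, 3 LacZ and 2 p35). Each slide was scanned in 1 run, so slide and scan are the same division. Groups and replicate numbers were taken from the sample titles.

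The scanner files hold 62976 spots per array, of which 61657 are not controls and belong to 32242 probes (26895 with 2 spots, 5067 with 1 and 280 with 10). The main measurement is the processed signal, a linear intensity that Agilent Feature Extraction 10.7.3.1 made by subtracting background and correcting surface trends, per the file headers and the submitters' processing notes, with no scaling between arrays. The median spot and local background intensity and the marks per spot were also used as deposited. Here the processed signal was put on the log2 scale, and the 75th percentile over non-control spots was subtracted from each array. That percentile ran from 707.3 to 1153 intensity units, with overlapping ranges in the 3 groups (707.3 to 1108 in GFP, 742.2 to 1153 in LacZ and 717.5 to 1100 in p35). Spots marked as outliers in the files (116 to 159 per array) were left out, except for 6 probe values with every spot so marked, and spots of a probe were averaged.

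The deposited table of the series holds log2 values of 37782 spots. It holds exactly the spots well above background on at least 5 of the 15 arrays. Each column correlated with the log2 processed signal of its own array at 0.9998 or more, which gives the scale and the direction. Column medians ran from 9.01 to 9.016, and the values lay within a median of 0.021 log2 units of a quantile normalization computed here, so the centring looks like that of quantile normalization, a step that none of the sources used here records. All 15 of its columns belong to samples and 0 do not, and it was used only as an alternative.

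The files give a systematic name for each probe and no gene name. Names were taken from a table of RefSeq genes of assembly Release 6, by RefSeq transcript accession without version (219 probes; 428 probes carry such an accession) or by a clone or transcript name that is a synonym of exactly 1 gene (168 probes). In all 387 probes were matched to 326 symbols, and 31855 probes were not. Most of these carry FlyBase transcript identifiers, which no table used here pairs with genes, so they are reported by identifier. The array headers name an older genome build (dm3), so no coordinates are given. Where several probes shared a target, the probe with the highest mean over the 15 arrays stood for it. Of the genes called in a contrast, CG31140 and CR31032 had a second probe above background on every array, and it gave the same direction in each called contrast. The other probes of CG7720 were above background on 0 arrays (mean log2 -8.72 and -8.27, against -1.24 for the probe used). They do not check its call, which rests on 1 probe.

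A target was tested if its probe was well above background (in at least 50% of its spots) on every array of at least 1 group, which left 14854 targets, 189 of them with a symbol. A linear model with 1 mean per group was fitted to all 15 arrays with lmFit and eBayes in limma 3.58.1 (R 4.3.3, statmod 1.5.0 and version 1.17.8 of data.table). Tests were two-sided, with Benjamini-Hochberg adjustment over targets and a threshold of 0.05. A target differed from both controls when it passed against GFP and against LacZ with the same sign. Where no array of a group was well above background, the difference is a bound, "at least N-fold". It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the target's own signal and the lowest signal among probes well above background on that array. That lowest signal is the most lenient detection limit of an array, so the bound holds for the processed signal only. Gene lists were tested with camera (preset correlation 0.01) and fry where at least 3 members were measured.

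The rule for named genes was fixed before the data were examined. It takes the 12 largest rises and 12 largest falls called against both controls, the largest differences between the controls, called members of the lists, and a set of caspase genes and w. Because few targets carry a symbol, it was applied among those with one, and at most 2 identifiers that were higher and 2 that were lower are printed per comparison. All list members measured are given with their values. Genes called in 1 contrast alone and FBtr0091660 were named after their values were seen.

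Alternatives fixed before the data were examined were quantile normalization, centring on the median over kept targets, the deposited series values, no filter on dim probes, a filter on all 15 arrays, the slide as a block and each slide alone, the replicate number as a block, fits on the 2 groups compared, the mean of all passing probes, an intensity trend with robust estimation, array weights, and leaving out each array in turn. The normexp background correction (offset 50) was planned on mean spot signals. It was run on median spot signals because the files used here hold no mean signal, and counts as chosen after seeing the data, like the exclusion of 3 and of 4 arrays.

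The pipeline was tested on simulated data with the spread of the real targets and 200 of 14854 targets changed in p35. For the calls against both controls it recovered 50% of 1.5-fold changes, 84% of 2-fold changes, 96% of 4-fold changes and 100% of 8-fold changes, each from 50 targets, with 1 false call among 14654 unchanged targets. Targets were drawn independently, so that number of false calls leaves out patterns that real arrays share over many targets. Each count of calls was also set against 100 splits of the same arrays, drawn with a fixed seed.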

Results

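RNA was measured in wing imaginal discs, the epithelial sacs of the Drosophila larva that form the adult wing and notum, taken from wandering larvae that the labels give as female. The yeast activator Gal4, expressed in the pattern of the C10 driver line, turned on 1 of 3 transgenes. These were p35, a baculovirus protein that inhibits effector caspases, or one of the inert reporters GFP and LacZ. Each group held 5 samples, each sample was RNA from 20 discs, and each was hybridised to its own 1-colour array. Between 56.8% and 63.9% of the spots of an array were well above background, and no spot was saturated. Pairs of arrays of the same group correlated at 0.985 to 0.995 across 14854 targets. A target is a gene symbol where a probe could be matched to one, and otherwise the transcript or cDNA identifier that the files give. Several identifiers may belong to 1 gene, so counts of targets are not counts of genes. Only 189 of the tested targets had a symbol, and levels are given on the log2 scale relative to the 75th percentile of the array. The number of arrays limits the precision of every value, and nothing in the labels says whether the samples of a group came from separate crosses, so the p-values cover the spread between these samples, which may be technical.

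The first question was which transcripts differed in discs expressing p35 from discs expressing either control protein. Among genes with a symbol, the long noncoding RNA lncRNA:CR33938 rose 2.11-fold against GFP and 1.95-fold against LacZ. Its level was 3.53 ± 0.07 in p35 discs, 2.45 ± 0.16 in GFP discs and 2.57 ± 0.04 in LacZ discs (SD, n = 5), with all 5 p35 arrays above all 10 control arrays. Pgant8, which encodes an enzyme that starts mucin-type O-glycosylation, rose by 0.40 on the log2 scale against GFP and by 0.45 against LacZ. The small nucleolar RNA snoRNA:Psi28S-2566, of a class that guides pseudouridylation of ribosomal RNA, fell by 0.45 against GFP and by 0.41 against LacZ, and CG31705 fell by 1.14 and by 0.42. For CG31705 the controls also differed, with GFP 0.72 above LacZ, more than the difference of p35 from LacZ. In limma's moderated test the adjusted p against GFP was 4.97e-07 for lncRNA:CR33938, 0.0112 for Pgant8, 0.00152 for snoRNA:Psi28S-2566 and 1.45e-05 for CG31705. Against LacZ it was 1.67e-06, 0.00383, 0.00213 and 0.0332 in the same order. For each of these 4 genes all 5 p35 arrays lay on the same side of all 10 control arrays, which is no separate evidence, since the genes were chosen for differing from both groups. The lncRNA:CR33938 calls also held within each slide taken alone. The Pgant8 and snoRNA:Psi28S-2566 calls held with the slide as a block and were lost within either slide alone, where the adjusted p reached 0.474 and 0.678 against GFP and 0.25 and 0.325 against LacZ. The Pgant8 call against GFP was also lost without the 3 arrays with high roX1 described further on. The log2 difference of Pgant8 from GFP stayed between 0.34 and 0.45 over the 31 alternative fits. The CG31705 call against GFP was lost within slide 2 alone (adjusted p = 0.0788), and its call against LacZ within either slide alone. The CG31705 call against LacZ was also lost on leaving out LacZ 1, LacZ 3, LacZ 5 or any 1 of the p35 arrays, with adjusted p from 0.0503 to 0.0895 and differences from -0.46 to -0.34 over the leave-one-out fits. In all it was lost in 15 of 31 alternative fits.

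**Figure D1:**
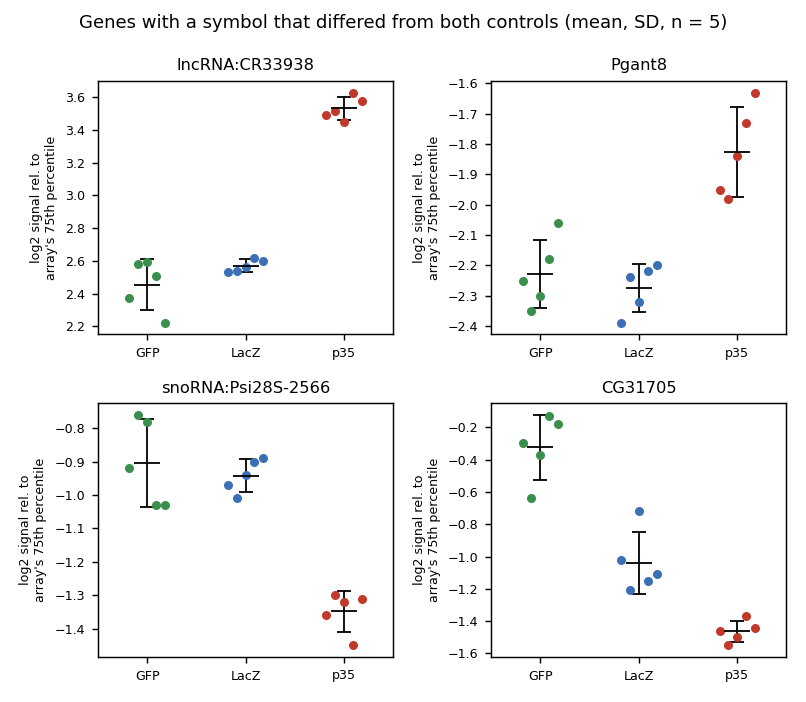
Log2 signal relative to the 75th percentile of the array (y axis) for the 4 genes with a symbol that differed from both controls, by group (x axis). Points are the 5 arrays of a group, and the bars give the mean and SD. The p35 arrays of lncRNA:CR33938 centre on 3.53, against 2.45 for GFP and 2.57 for LacZ.

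The largest differences were in transcripts without a symbol. FBtr0072956 was 17.9-fold higher in p35 discs than in GFP discs and 28.4-fold higher than in LacZ discs, with levels of -1.06 ± 0.20, -5.22 ± 0.38 and -5.89 ± 0.20 (SD, n = 5), and adjusted p of 1.63e-09 and 1.31e-10. BP558039 was 13.2-fold and 20.8-fold higher (adjusted p = 1.45e-08 and 1.49e-09). TC245814 was not well above background on any p35 array. By the processed signal it was at least 53.5-fold lower than in GFP discs and at least 26.2-fold lower than in LacZ discs (adjusted p = 2.96e-08 and 2.71e-07). TC229046, well above background on 1 of the 5 p35 arrays, lay lower by 3.51 and 3.63 log2 units as fitted (adjusted p = 9.92e-09 and 2.77e-09). These 4 targets kept their calls in every alternative that gave a value for them, but the sizes depended on the handling of background. With normexp background correction, chosen after seeing the data, which adds an offset of 50 to each signal, the log2 differences from GFP and LacZ were 2.47 and 2.59 for FBtr0072956. They were -2.12 and -1.41 for TC245814 and -0.73 and -0.80 for TC229046. For BP558039 the difference from LacZ was 3.69. None of the 12 largest rises and 12 largest falls carried a symbol. In 2 of these rises and 6 of these falls a group had no array well above background, so that their sizes are bounds.

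Of the 14854 targets, 247 differed from both controls in the same direction, 121 higher and 126 lower in p35 discs. Which direction had more targets depended on the scaling, with 128 higher and 102 lower after quantile normalization. Of these 247 targets, 69 differed at least 2-fold from both. The 2 contrasts share the p35 arrays, and 50 simulations of unchanged groups against shared arrays gave 0 such targets. Each target was drawn independently there, while real arrays share patterns over many targets, so the simulations do not give the false calls of these data. Independent lists of the same sizes would share 3.61 higher and 5.45 lower targets. When the p35 arrays were divided into 2 and 3, with one part set against GFP and the other against LacZ, between 29.5 and 39 targets passed in both over the 10 divisions, each averaged over both assignments. The log2 differences of the 2 contrasts correlated at 0.544 across targets, which are not independent replicates, against 0.499 in the simulations. Their covariance was 0.0648 against 0.0157 simulated, and 0.0516 with the p35 arrays divided. With the slide as a block, 306 targets were called against both controls, and with the replicate number as a block 373. Within slide 1 alone there were 39, and within slide 2 alone 17. Without a filter on dim probes 161 were called, with normexp background correction 154, and without the 3 arrays with high roX1 128.

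**Figure D2:**
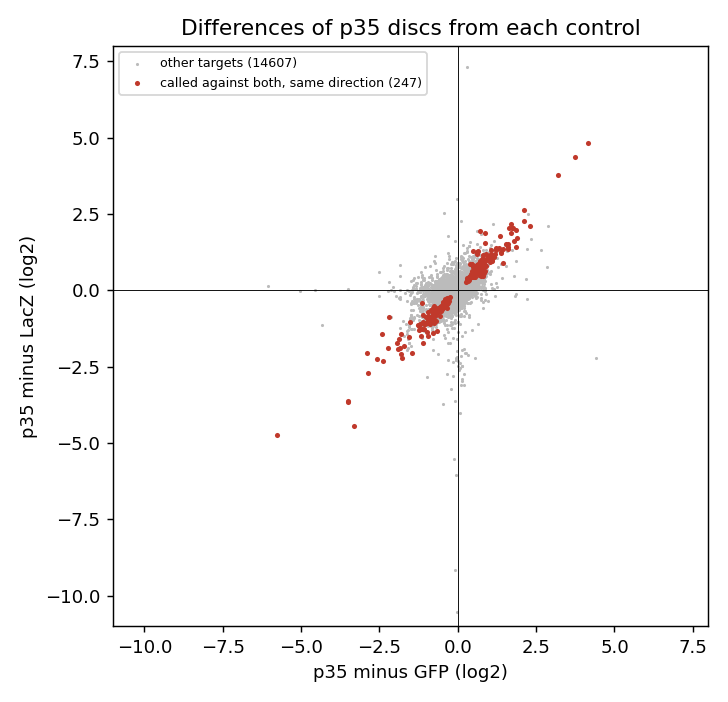
Log2 difference of each target between p35 and GFP discs (x axis) and between p35 and LacZ discs (y axis), 1 point per target. Red points are the 247 targets called against both controls in the same direction, and grey points are all others. The red points follow the diagonal, and grey points far from the origin along 1 axis are targets in which a control group stood apart.

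Against GFP alone, CG8204, CHKov1 and Ald1 were the genes with a symbol that passed the test in this contrast and not against LacZ. The difference between these contrasts is that of GFP from LacZ, which passed the test for CG8204 (adjusted p = 0.0131) and not for CHKov1 (0.501) or Ald1 (0.655). CG8204 was 1.83-fold higher in p35 than in GFP discs (log2 difference 0.87, adjusted p = 0.00399), and its level in LacZ discs, -0.34 ± 0.23, was near that of p35 discs, -0.25 ± 0.12 (SD, n = 5). Ald1, which encodes the glycolytic enzyme fructose-bisphosphate aldolase, was 1.26-fold higher (adjusted p = 0.0229), with all 5 p35 arrays above all 10 control arrays. CHKov1 was 1.51-fold lower (adjusted p = 0.0303). All 3 calls were lost within either slide alone. The Ald1 call was also lost on leaving out GFP 1, GFP 2, GFP 4, GFP 5, p35 1 or p35 2 (adjusted p from 0.0505 to 0.0701), and the CHKov1 call on leaving out GFP 1, GFP 3, GFP 5, p35 3, p35 4 or p35 5 (adjusted p from 0.0632 to 0.0874). Each of these 2 calls was lost in 12 of 31 alternative fits. In all, 443 targets differed, 186 higher and 257 lower in p35 discs, and 138 of them by at least 2-fold. The balance of directions depended on the scaling, with 213 higher and 206 lower after quantile normalization and 201 and 190 in the series values. The count was 509 with the slide as a block, 87 within slide 1 and 25 within slide 2. It was 291 without a filter on dim probes, 265 with normexp, 254 without the 3 arrays with high roX1 and 671 with array weights.

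Against LacZ, cype, which encodes a subunit of cytochrome c oxidase, was 1.76-fold lower in p35 discs (log2 difference -0.82, adjusted p = 0.000168). Its level was -0.96 ± 0.20 in p35 discs, -0.14 ± 0.16 in LacZ discs and -0.91 ± 0.07 in GFP discs (SD, n = 5), so that LacZ was the group apart. The pseudogene CR14798 was 1.74-fold lower in p35 than in LacZ discs (log2 difference -0.80, adjusted p = 0.00766). GFP differed from LacZ by the same test for cype (adjusted p = 0.000445) and not for CR14798 (0.453). Both of these calls held when any 1 array was left out. The cype call was lost within slide 2 alone, and the CR14798 call within either slide alone and without the 3 arrays with high roX1. The other 6 genes with a symbol called against LacZ alone were less stable, each lost in 9 to 17 of 31 alternative fits. CG31140, CG7720 and lncRNA:mimi were higher in p35 than in LacZ discs, with log2 differences of 0.80, 0.48 and 0.51. CG12971, CR31032 and lncRNA:CR32218 were lower, with -1.07, -0.37 and -0.54 (adjusted p from 0.0213 to 0.0375). From GFP, p35 differed by only 0.17 for CG31140, -0.09 for CG12971, 0.02 for CR31032 and -0.01 for lncRNA:CR32218. GFP differed from LacZ by 0.63, -0.98, -0.39 and -0.53 in that order, and only CR31032 was called. For CG7720 and lncRNA:mimi, p35 lay 0.30 and 0.20 above GFP. All 6 calls were lost on leaving out p35 2 or p35 3, and each on leaving out other single arrays among GFP 5, LacZ 2 to LacZ 5 and the p35 arrays (adjusted p from 0.0509 to 0.106). The CG31140 call was also lost with the slide or the replicate number as a block, and the lncRNA:mimi call with the replicate block. In all, 603 targets differed, 288 higher and 315 lower in p35 discs, and 197 of them by at least 2-fold. With arrays centred on their median, 307 were higher and 301 lower. The count was 683 with the slide as a block, 82 within slide 1, 71 within slide 2, 390 with normexp and 367 without the 3 arrays with high roX1.

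The 2 control groups, which both express an inert protein, were compared with each other to measure how far control discs differ. Among genes with a symbol, CG31705 was 1.64-fold higher in GFP than in LacZ discs, and cype, CG8204 and the pseudogene CR31032 were 1.71-fold, 1.73-fold and 1.31-fold lower. Limma's adjusted p was 0.00126, 0.000445, 0.0131 and 0.0367 in that order, and all 4 calls were lost within either slide alone. The CG8204 call was also lost without the 3 arrays with high roX1 and in the fit on the arrays of the 2 groups alone. The log2 difference of CG8204 between GFP and LacZ stayed between -0.91 and -0.65 over the 31 alternative fits. The CR31032 call was lost in 12 of the 15 leave-one-out fits, all but those without LacZ 1, p35 1 or p35 4 (adjusted p from 0.0509 to 0.0999), and in 18 of 31 alternative fits in all. FBtr0080934 and FBtr0308804 were not well above background on any GFP array and were at least 1260-fold and at least 467-fold higher in LacZ discs (adjusted p = 1.07e-11 and 1.07e-10). TC244250 was not well above background on any LacZ array and was at least 47-fold higher in GFP discs (adjusted p = 2.91e-10). FBtr0076403, well above background on 1 of the 5 LacZ arrays, was 130-fold higher in GFP discs as fitted (adjusted p = 1.09e-09). These bounds and sizes hold for the processed signal. With normexp the log2 differences of GFP from LacZ were -5.59 for FBtr0080934, -4.50 for FBtr0308804, 1.86 for TC244250 and 3.40 for FBtr0076403, and all 4 calls held. In all, 197 targets differed, 111 higher and 86 lower in GFP discs, 97 of them by at least 2-fold and 48 by at least 4-fold. With quantile normalization 102 were higher and 110 lower, and in the series values 97 and 102. The p35 discs lay within 1 log2 unit of GFP, with no call against GFP, in 38 of these 48 targets, and within 1 log2 unit of LacZ, with no call against LacZ, in 8. The count was 221 with the slide as a block, 28 within slide 1, 21 within slide 2 and 127 with normexp. Without GFP 1, GFP 5, LacZ 1 and LacZ 3, arrays whose values are described further on, it was 122.

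Counted for each group against both others, 247 targets set p35 apart, 116 set LacZ apart and 56 set GFP apart. The root mean square deviation of the arrays from their group mean was 0.258 log2 units in p35, 0.303 in GFP and 0.33 in LacZ. The order of the groups changed with the size of the difference. At 4-fold or more from both other groups there were 36 targets for LacZ, 14 for p35 and 9 for GFP. Without GFP 1, GFP 5, LacZ 1 and LacZ 3 the counts at any size were 170 for p35, 67 for LacZ and 45 for GFP, and at 4-fold or more 13, 23 and 7. Without the 3 arrays with high roX1 they were 128, 95 and 49, and at 4-fold or more 12, 35 and 9.

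**Figure D3:**
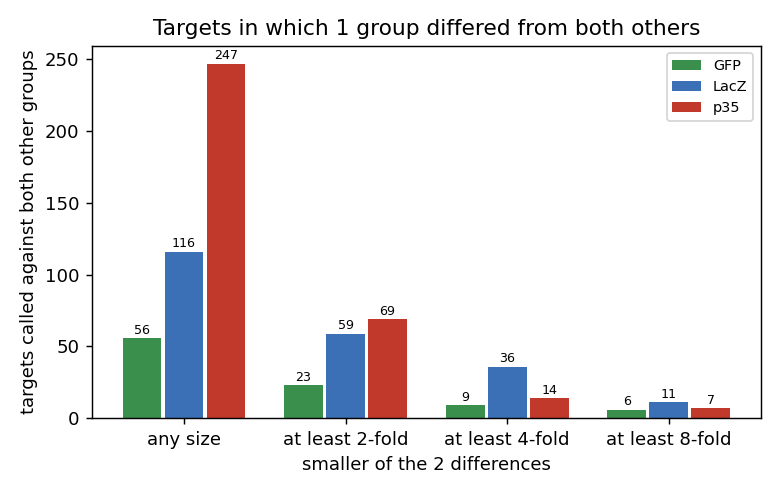
Number of targets called in 1 group against both other groups (y axis), by the minimum of the smaller of the 2 differences (x axis) and by group. At any size p35 has the most, 247, and at 4-fold or more LacZ has the most, 36.

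The gene lists fixed for this tissue could be examined only through the few members with a symbol. Of the 39 lists, 28 had no measured member, 10 had 1 or 2, and 1 had at least 3. None of the 14 distinct members differed from both controls. Of all targets only 1.66% did, so this says little about these pathways. The cytosolic ribosomal protein list held RpL23, RpS18 and RpS29, with log2 differences of p35 discs of -0.04, 0.02 and 0.25 from GFP and -0.07, -0.01 and -0.06 from LacZ. The probe of RpS29, matched by a synonym, read -4.842 in GFP, -4.535 in LacZ and -4.596 in p35 discs. That is far below RpL23 (6.724 to 6.792) and RpS18 (6.189 to 6.218). Whether this probe reads the RpS29 mRNA was not tested, so the list may rest on fewer members. No shift of the list in p35 discs against the mean of the controls was detected (camera p = 0.957 with the preset correlation, 0.97 with an estimated correlation, and fry p = 0.994). The respiratory chain genes UQCR-C2 and RFeSP gave 0.05 and 0.11 against GFP and 0.04 and 0.07 against LacZ, with no call. Among patterning genes, the Hedgehog receptor gene ptc gave 0.20 and 0.18, the Dpp pathway regulator shn 0.07 and 0.04, the EGFR target kek1 0.15 and 0.20, and the Notch target E(spl)mbeta-HLH -0.02 and -0.19, against GFP and LacZ in turn, and none was called. The eye disc gene eya gave -0.26 and -0.15, the epithelial regulator grh, held in the tracheal list, 0.10 and 0.06, and the laminin gene LanA -0.32 and -0.30, also without a call. In the glycolysis list Ald1, its only measured member, was called against GFP alone. Adjusted over the list alone, which for a list of 1 is the unadjusted p, Ald1 and kek1 passed 0.05 against both controls, and no member of any other list did. Several of these differences rested on the control arrays GFP 1, GFP 5, LacZ 1 and LacZ 3. Without them kek1 gave 0.08 and 0.13, LanA -0.10 and -0.09, and ptc 0 and -0.07, and shn, grh and eya changed sign in at least 1 contrast. None of the caspase genes Nc, Ice and Dcp-1, the inhibitor gene th, the adaptor gene Ark and the eye colour gene w was matched to a probe here.

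2 features of single arrays cut across the groups. The male-specific roX1 RNA, part of the dosage compensation complex of the male X chromosome, gave 0.65 in GFP 3, 1.36 in LacZ 1 and 1.10 in p35 3, and between -4.65 and -3.74 in the other 12 arrays. Its group means did not differ (adjusted p = 0.985 against GFP and 0.95 against LacZ). The second is a set of targets that separated GFP 1, GFP 5, LacZ 1 and LacZ 3 from the other 11 arrays. LanA read 4.37 to 4.46 in these 4 arrays and 3.64 to 4 in the others, ptc -1.41 to -1.26 against -0.93 to -0.65, and kek1 3.32 to 3.43 against 3.50 to 3.75. FBtr0091660, chosen after its values were seen, read -0.37 to 0.28 against -4.95 to -3.84. No p35 array was among the 4. Without these 4 arrays, 356 targets were called against GFP, 421 against LacZ and 170 against both. Without the 3 arrays with high roX1, the counts were 254, 367 and 128. Both exclusions were chosen after seeing the data.

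**Figure D4:**
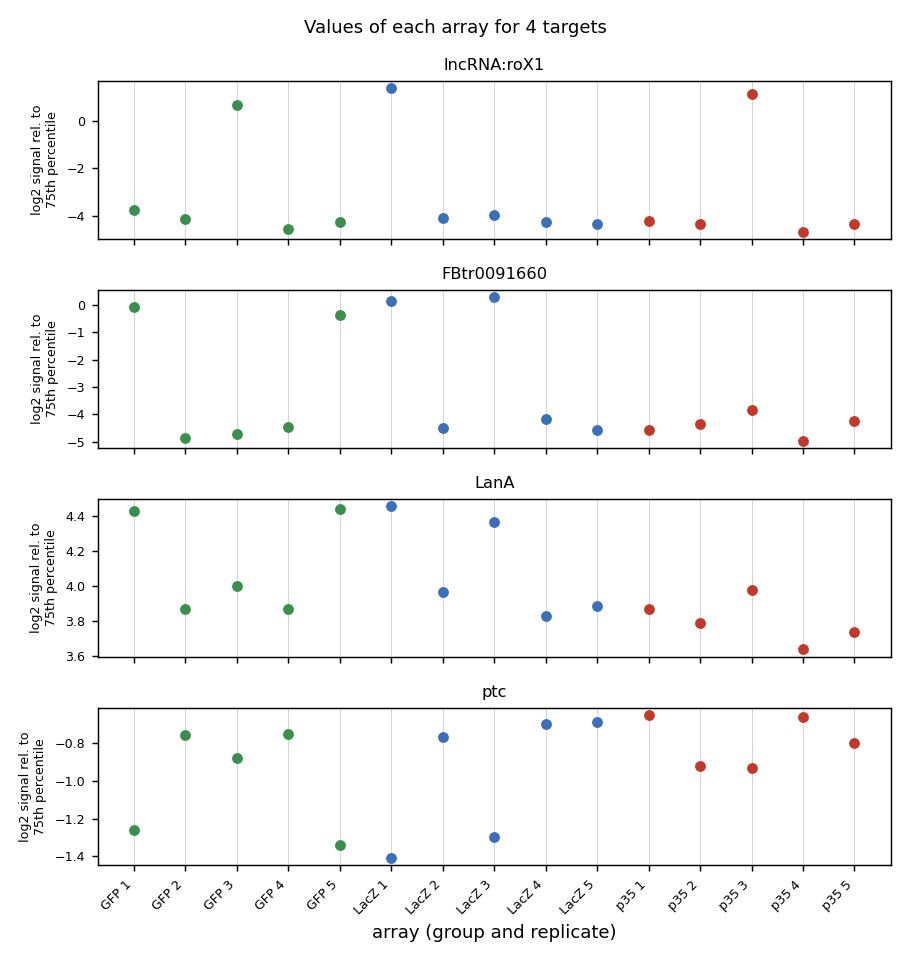
Log2 signal relative to the 75th percentile of the array (y axis) of each of the 15 arrays (x axis, coloured by group) for roX1, FBtr0091660, LanA and ptc. roX1 lies between 0.65 and 1.36 in GFP 3, LacZ 1 and p35 3 and at or below -3.74 elsewhere, while GFP 1, GFP 5, LacZ 1 and LacZ 3 stand apart in the other 3 panels.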

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

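The tests of slide and of male discs below, that of p35 expression, and the count over choices of 4 arrays were chosen after the values were seen. Over the 36 named targets, 108 groups of 5 arrays were examined for a single array far from the rest, and 8 were found, where chance alone marks about 1 in 20 groups.

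3 of the 8 are roX1. The gap of the highest array to the nearest other, as a share of the range of its group, was 0.848 for GFP 3, 0.932 for LacZ 1 and 0.926 for p35 3, and these arrays lay 21-fold, 39.5-fold and 39.9-fold above the nearest array of their group. The labels describe the larvae as female. A candidate explanation is that these 3 samples hold discs of males, since roX RNAs accumulate in males. All 6 probes matched to roX1 and roX2, separate genes on the X chromosome, ranked the same 3 arrays highest, as male discs would require, and 5 arrays on the same slide read low, which argues against a slide effect. How many of the 20 discs were male stays open, because no sample of known male share was measured. Each of the 3 groups holds 1 of these arrays.

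Ald1 in GFP 3 (ratio 0.712) and in LacZ 3 (0.813) lay 1.16-fold and 1.12-fold from the nearest array of its group. TC245814 in p35 2 (0.836), FBtr0080934 in GFP 1 (0.764) and FBtr0308804 in GFP 3 (0.789) were single arrays apart within groups in which no array was well above background.

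A second pattern was the set of targets in which GFP 1, GFP 5, LacZ 1 and LacZ 3 read apart. The first principal component of the deviations from the group means carried 30.2% of their variance, with scores of -31.65 to -14.75 in these 4 arrays and -4.862 to 24.19 in the other 11. Over all 100 choices of 2 GFP and 2 LacZ arrays, the number of targets in which the chosen arrays lay all above or all below the other 11 had a median of 10 among the other choices. It was 3225, or 21.7% of targets, for these 4, and the next highest was 250. Both slides, 2 of 2, hold arrays of each kind, which argues against slide or scan, and 1 of the 3 arrays with high roX1 is among the 4, which argues against male discs. With quantile normalization the number for these 4 was 3282, and the highest for any other choice 269, which argues against the scaling of the arrays. Membership among the 4 cannot tell a link to p35 from chance with so few arrays. 4 of 10 control arrays and 0 of 5 p35 arrays were members (Fisher's exact test, two-sided, p = 0.231). Deviations from group means cannot show where p35 lies on this axis. On the first component without that centring, these 4 arrays scored -43.81 to -14.45 and the other control arrays -5.567 to 13.02. All p35 arrays lay beyond them, at 14.65 to 24.17. That component also holds the differences between groups, so a link to p35 stays open. A difference in the stage of the larvae or in the tissue dissected was not tested, because the lists of stage and tissue markers had at most 1 measured member each.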

How the results depend on the processing

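The normexp setting and the exclusions of 3 and of 4 arrays were chosen after seeing the data. For p35 against GFP (443), p35 against LacZ (603), p35 against both (247) and GFP against LacZ (197), counts stayed within 1.5 times under quantile normalization, median centring, the deposited series values, the filter on all 15 arrays, the slide as a block, fits on 2 groups, the mean of all probes, and the trended robust fit. Without a filter on dim probes 291 targets were called against GFP and 161 against both. Normexp gave 265 against GFP, 390 against LacZ, 154 against both and 127 for GFP against LacZ. Array weights gave 671 against GFP. The cause was not tested. Slide 1 alone gave 87, 82, 39 and 28, and slide 2 alone 25, 71, 17 and 21, in the order GFP, LacZ, both, GFP against LacZ, with fewer arrays in each. Without the 3 arrays with high roX1, 254 were called against GFP, 367 against LacZ and 128 against both, and without the 4 control arrays that stand apart 122 for GFP against LacZ, again with fewer arrays. Leaving out 1 array gave 312 to 454 against GFP, 438 to 613 against LacZ, 179 to 246 against both and 153 to 209 for GFP against LacZ. Correlations of deviations between same-numbered arrays ran from -0.382 to 0.534 and were above 0.1 in 12 of 15 pairs. Of the 15 arrays, 3 correlated best with their own number in both other groups. The main fit did not pair the samples by number, but these values do not exclude a pairing. Above 0.1 were 3 of 5 pairs of GFP with LacZ, 4 of 5 of GFP with p35 and 5 of 5 of LacZ with p35, so a pairing is left open, most of all for the last. Arrays of the same number shared a slide except for LacZ 3. The mean correlation was 0.0834 on the same slide and -0.0811 on different slides. A pairing by number is thus hard to tell from a shared slide. With the replicate block the counts were 632 against GFP, 786 against LacZ, 373 against both and 244 for GFP against LacZ. The scan was not run as a separate block, because it coincides with the slide. For p35 against the mean of the controls, camera made 0 calls for the 1 list tested in all 31 fits run (lowest unadjusted p 0.525, in the series values). It made none with an estimated correlation (p = 0.97), nor did fry (p = 0.994), both run only in the fit to all arrays. The 39 called differences of named targets kept call and direction in 527 of 612 values under the 16 alternatives and in 518 of 585 leave-one-out values, and none reversed. Sizes of targets near background fell with normexp. Targets with no array of a group well above background carry bounds only. FBtr0076403 and TC229046, above it on 1 array of a group, are given as fitted, largely against background signal. At 1.5-fold the simulated recovery was 50%, so small changes can be missed.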

Other observations

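The test of the genetic background, the exclusions of 3 and of 4 arrays, the sizes of the differences without the 3, and the comparison with other left-out trios of arrays were chosen after the counts were seen. Small structural RNAs and pseudogenes were among the few genes with a symbol. Of 12 measured small structural RNAs, 1 (snoRNA:Psi28S-2566) differed from both controls, as did 1 of 23 long noncoding or antisense RNAs (lncRNA:CR33938), 2 of 149 protein-coding genes (Pgant8 and CG31705) and 0 of 5 pseudogenes. Of the 5 pseudogenes 2, CR14798 and CR31032, were called against LacZ and 0 against GFP. These classes were formed after the names were seen and were not tested for enrichment.

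The third pattern weighed is that p35 discs stood apart from both controls in 247 targets. Among 100 splits of the 15 arrays into 3 groups of 5, the real one alone gave as many (1 of 100, highest other split 91, which set the 5 LacZ arrays apart). The same held for p35 against GFP (443, 1 of 100 splits, highest other 6) and p35 against LacZ (603, 1 of 100 splits, highest other 1). A random division of these arrays is therefore unlikely to give these counts. Chance between crosses is not excluded, since the samples of a group may be technical and mixed splits widen the spread within groups. For GFP against LacZ (197) 6 of 100 splits gave as many, with 3566 the highest other, so chance cannot be excluded by this count. The 5 splits besides the real one all placed GFP 1, GFP 5, LacZ 1 and LacZ 3 on the same side, with counts from 3044 to 3566, which points to a structure of the samples, and the highest of the remaining splits was 1. The 4 control arrays that stand apart are unlikely to make up the p35 result, because 170 targets were still called against both controls without them, 140 of them also called with all arrays.

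Without GFP 3, LacZ 1 and p35 3, the arrays with high roX1, 128 targets were called against both controls, 126 of them among the 247. This count decides nothing about male discs as a source of the p35 differences, since each group holds 1 of these arrays and leaving out other trios also ended calls (3 of 100 choices, this one included, gave as few, with a median of 149 and a range of 122 to 197 over the others). The sizes do not decide about male discs either. All 247 targets kept at least 63.9% of both log2 differences without these arrays, but they were selected with all arrays. A difference carried by 1 array per group would hardly pass that selection. In the 121 targets that lost the call, the median size went from 0.61 (quartiles 0.43 and 0.86) to 0.59 (0.44 and 0.85) against GFP and from 0.62 (0.47 and 0.94) to 0.63 (0.43 and 0.94) against LacZ. The median standard error rose from 0.13 to 0.14 in both contrasts, and fewer arrays were compared, so the calls ended with little change in size.

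A hypothesis for the largest differences is that they come from the genetic background of each transgenic line, such as local sequence changes or insertions, and not from caspase inhibition. At 4-fold or more from both other groups, p35 had 14 targets, against 36 for LacZ and 9 for GFP. More targets thus differed this much in the LacZ line than in the p35 line, and fewer in the GFP line. Several targets may belong to 1 gene, so these counts do not rank the lines by separate differences. Without the 4 control arrays that stand apart these counts were 13, 23 and 7. Each transgene is carried by 1 line, so line and transgene cannot be told apart. Which of the 247 targets follow from caspase inhibition stays open.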
